A study of Homo sapiens with 6 samples.

How the data were processed

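RNA sequencing of U2932 lymphoma cells was compared between 3 samples with a hairpin against PRDM11 and 3 with a scrambled hairpin. Cells were selected with puromycin for 3 days, and RNA was extracted on columns with DNase digestion, per the labels' protocols. Reads were processed with STAR, HTSeq 0.5.4p5 and DESeq 1.14.0 on build hg19, per the submitters' processing notes. The roles of these tools, the annotation release and the strand setting are not given in the sources used here. Antisense and overlapping genes therefore cannot be told apart with certainty.

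Per the file headers, the deposited table holds for 34675 genes a mean over both conditions, a mean of condition A and of condition B, a fold change, its log2, a p-value and an adjusted p-value. The means are a signal in normalised reads, that is, read counts that the authors divided by size factors, per the file headers. The deposited fold is the ratio of condition B to condition A, and the deposited log2 ratio is its logarithm, as recomputed from the means. The log2 ratio is given in the text with its sign turned, as condition A over condition B. The deposited adjusted p-value was the Benjamini-Hochberg adjustment over all rows, as recomputed. A second deposited file, an hg19 track per its header, lists 221491 coding intervals with a score. The deposited score was 30 times the negative log2 of the gene's p, held at 1000, as recomputed, and was not used further. Interval ends were counted from 1, since 97.6% of intervals matched coding lengths on that reading. No column of values per sample was present in the tables used, so 0 such columns were left out.

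The conditions are named A and B only. They were not assigned to the knockdown or the scrambled control, because no header or label does so and a gene's value may not decide it. The design written before the data were examined assumed read counts per sample. The files hold the comparison alone, so the rule set for that case was followed: the deposited adjusted p at 0.05 gave the calls, and gene lists were tested on signed z values from the deposited p. The standard error of a log2 ratio was taken as its size divided by that z. It is an approximation, since DESeq does not use a normal test.

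Because each mean is a sum of 3 whole numbers with fixed weights, printed with 15 digits, the reads of each library could be recovered by an integer search. Weights came from genes with a single read. Means up to 10000 were searched, and 31014 of 31051 rows gave 1 solution in condition A and 30955 of 30955 in condition B. Above a mean of 1500, only solutions with each library at 0.7 to 1.4 times the condition's mean were accepted. On simulated means of condition A and of condition B, 99.8% of 2836 and 99.9% of 2847 genes were recovered, with 0 wrong. The recovered reads came to 28146447, 23772887 and 18132989 in the libraries of condition A and 26449843, 25047200 and 22578855 in condition B. These rows hold 53.3% of the summed mean in condition A and 57.2% in condition B, so the totals are not the full depth. The libraries of each condition are numbered by falling size factor, and the numbers match no replicate number of the labels.

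The text names PRDM11, FOS and JUN, the 12 largest increases and 12 largest decreases with adjusted p under 0.05, a mean of at least 50 and a symbol, pseudogenes left out, up to 4 members with the smallest p of each list, and the 5 genes with the smallest p. Members of a list that make up its calls are named where they are few, and those outside this rule were picked after their values were seen. Some genes that the rule names are not reported here. Symbols came from the deposited table, which gives 17231, and from GENCODE 29, which matched 32587 gene identifiers and was used for gene types and transcript lengths. The 25 lists fixed before the data were examined cover immediate early and AP-1, PRDM, MYC-activated growth, germinal centre, plasma cell, NF-kB, interferon-stimulated, p53, mitotic, DNA replication, BCL2 family, MHC class II, B cell receptor and identity, unfolded protein response and ATF4, cholesterol synthesis, glycolysis and hypoxia, heat shock, ribosomal protein, mitochondrially encoded, histone, cytokine and chemokine, adhesion and migration, T and NK cell, myeloid, and epithelial and fibroblast genes.

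Lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 against all other genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 24 lists with a row. The test was checked with random lists of 25 genes on the z values of the 34675 genes. Of 1000 such lists 3.1% had p under 0.05, and 12.2% did when the lists were drawn from genes with a mean of at least 100. Tested within those genes the share was 3.1%. Of 200 lists of those genes with an added shift in z, 99.5% were found, but these were tested against all genes. The shift was larger than the mean z of most of the fixed lists, so the share does not tell how often smaller shifts are found. An estimated correlation below 0 was set to 0. Lists of well expressed genes are therefore called too often against all genes, and the results among genes with a mean of at least 100 are given where they end a call.

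Alternatives planned before the data were examined were means of at least 10 or 100 with p adjusted again, adjusted p under 0.01 or 0.10, an added 1.5-fold minimum and log2 ratios centred on their median. Added after the data were seen were a limma test of log2 of the recovered normalised reads plus 1 over 16629 genes with a mean of at least 10, leaving out each library in turn, list tests with the correlation estimated from the recovered libraries, that estimate among genes with a mean of at least 100, and list tests on ranks. In simulated libraries of condition A against condition B over 16629 genes, limma recovered 97% of genes changed 2-fold and 84% of those changed 1.5-fold, with 11 false among 192 calls. The changed genes all had a mean of at least 50, and a dispersion of 0.01 was set for every gene. Genes with fewer reads or a wider spread are not covered by these rates. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the remaining steps, and matplotlib 3.10.9 for figures.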

Results

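U2932 is an established human cell line from a diffuse large B cell lymphoma. Gene expression was measured by RNA sequencing after infection with a short hairpin RNA against PRDM11 (3 samples) or a scrambled hairpin (3 samples), each selected with puromycin for 3 days. PRDM11 belongs to the PR domain family of transcription and chromatin regulators, and the comparison asks which genes change when it is depleted. The values came as 1 comparison of 34675 genes between conditions named only A and B. Neither the header nor the labels say which of them is the knockdown, so every difference is given as condition A relative to condition B. The normalised means summed to 43812481 reads in condition A and 41847907 in condition B. Whole reads of 3 libraries per condition could be recovered from the means, and the libraries of condition A had size factors of 1.21, 1.03 and 0.768 against 1.09, 1.05 and 0.951 in condition B. The labels do not say that the samples came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

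PRDM11 differed clearly between the conditions. In the authors' deposited table its mean was 287.6 normalised reads in condition A and 542.1 in condition B, a log2 ratio of -0.91 with a standard error of 0.14 implied by the deposited p (DESeq adjusted p = 1.76e-08). The 3 recovered libraries of condition A held 268, 272 and 323 normalised reads of PRDM11, below the 565, 516 and 545 of condition B, and the log2 ratio stayed between -1.01 and -0.87 with any 1 library left out. PRDM11 (ENSG00000019485) has its coding intervals on chromosome 11 from 45117357 to 45246456 in build hg19, in 9 separate blocks. PRDM11 was 1.88-fold higher in condition B in the authors' deposited table, and assigning the knockdown to condition A would rest on this value alone.

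FOS and JUN, which encode subunits of the AP-1 transcription factor, were both higher in condition A. They were chosen for report before the data were examined, but from published work on PRDM11 that followed them. The choice, and the immediate early and AP-1 list that holds both, is therefore not independent of the study. FOS (ENSG00000170345, chromosome 14, coding intervals 75745686 to 75748124) had 671.3 normalised reads in condition A and 172.5 in condition B in the authors' deposited table, a log2 ratio of 1.96 with an implied standard error of 0.15 (DESeq adjusted p = 5.9e-37, the smallest of all genes). JUN (ENSG00000177606, chromosome 1, 59247750 to 59248742) had 781.2 and 324.8 in the authors' deposited table, a log2 ratio of 1.27 with an implied standard error of 0.14 (DESeq adjusted p = 3.13e-17). The recovered libraries of condition A held 643, 693 and 678 normalised reads of FOS against 168, 165 and 185 in condition B. EGR1, a zinc finger factor induced within minutes of stimulation, was 8212 in condition A and 2108 in condition B in the authors' deposited table (log2 ratio 1.96, DESeq adjusted p = 7.29e-21).

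**Figure D1:**
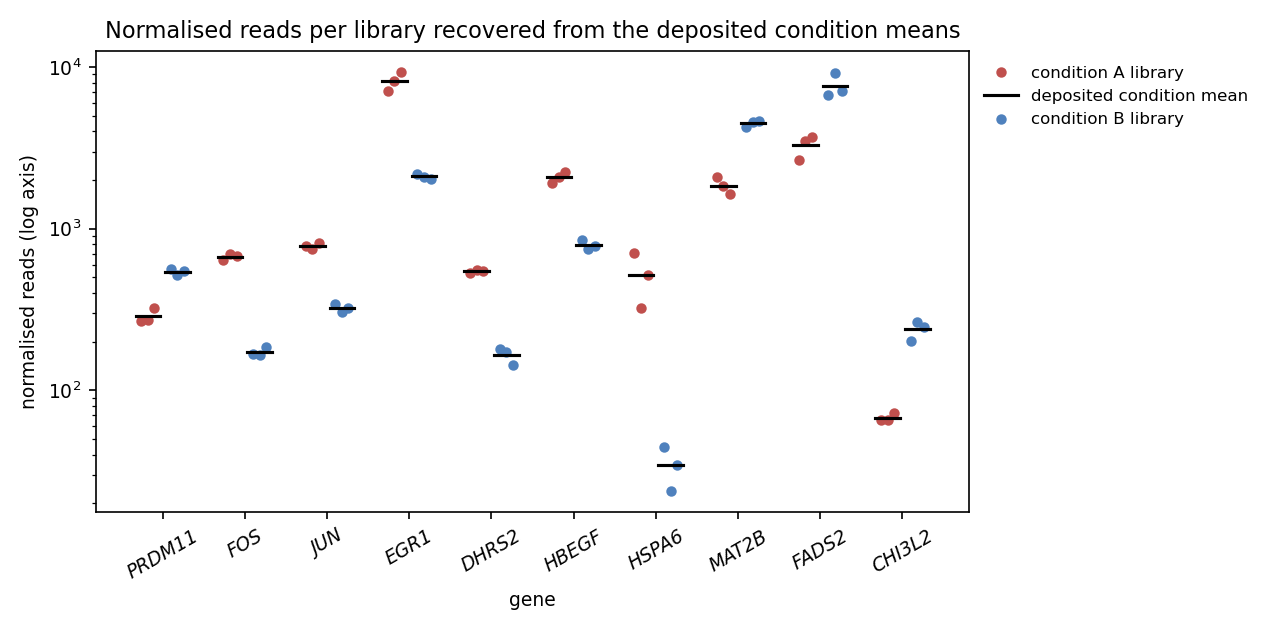
Normalised reads per library (log axis) for PRDM11 and 9 other genes of the text, with condition A in red and condition B in blue, 3 libraries each, and a black bar at the deposited mean of each condition. PRDM11 lay at 268 to 323 in condition A and 516 to 565 in condition B, and FOS at 643 to 693 against 165 to 185.

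Across the genome 881 genes passed an adjusted p of 0.05 in the authors' deposited table, 335 of them higher and 546 lower in condition A. Protein-coding genes made up 732 of these, 254 higher and 478 lower. A further 21 called genes, 13 higher and 8 lower and HIST1H4I and CCL3 among them, had no matched gene type, so 732 may be too few. At least 2-fold differences were found in 121 genes, 62 higher and 59 lower, and at least 1.5-fold differences in 488. Reads per library were recovered for 823 of the 881 genes. In all 823 the 3 libraries of one condition lay on one side of the 3 of the other, as did 30.1% of genes with a mean of at least 50 that were not called, against 10% by chance. The 823 were called from these same libraries, so their separation is no independent check of the calls. The log2 ratio of 10 of the 823 moved by over 1.5-fold with 1 library left out, that of PHLDA3 among them. A condition mean above 1500 could not move so far. There the search accepted only libraries at 0.7 to 1.4 times the mean. A limma test of the recovered reads, added after the data were seen, called 1535 genes and shared 815 of the 817 deposited calls among the genes it tested, and it called 387 genes without library 2 of condition A, 367 without library 2 of condition B and 387 without library 3 of condition B.

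The largest increases among genes with a mean of at least 50 included stress, histone and signalling genes. HSPA6, an inducible member of the HSP70 chaperone family, had 515.1 normalised reads in condition A and 34.5 in condition B in the authors' deposited table (log2 ratio 3.90, implied standard error 0.66, DESeq adjusted p = 1.56e-06). Its recovered libraries spread widely within condition A, from 324 to 706, and lay at 24 to 45 in condition B. APOL5, an apolipoprotein L gene, had a log2 ratio of 2.05, the histone gene HIST1H4I 1.93 and DHRS2, a short-chain dehydrogenase, 1.72 in the authors' deposited table. HBEGF, a ligand of the epidermal growth factor receptor, was 2076 against 791.2 in the authors' deposited table (log2 ratio 1.39, DESeq adjusted p = 8.24e-25). The histone gene HIST1H2BF, the matrix proteoglycan gene PRELP and CYP26A1, an enzyme that degrades retinoic acid, had log2 ratios of 1.41, 1.35 and 1.26 in the authors' deposited table.

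The largest decreases in condition A were those of L3MBTL4, which encodes a protein with malignant brain tumour repeats, C6orf223 and CHI3L2, a chitinase-like gene. Their log2 ratios in the authors' deposited table were -2.19, -1.92 and -1.81. CHI3L2 had 67.9 normalised reads in condition A and 237.8 in condition B (DESeq adjusted p = 1.4e-17 in the authors' deposited table). MAT2B, the regulatory subunit of methionine adenosyltransferase, had 1847 in condition A and 4476 in condition B in the authors' deposited table, a log2 ratio of -1.28 (DESeq adjusted p = 6.49e-22). FADS2, a desaturase of polyunsaturated fatty acid synthesis, had 3277 and 7658 in the authors' deposited table (log2 ratio -1.22, DESeq adjusted p = 1.77e-05). The others of the 12 largest decreases were DOC2A, OPLAH, SFN, FNDC1, VSIG10, ARL2 and VAT1L, with log2 ratios from -1.79 to -1.19 in the authors' deposited table.

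Immediate early and AP-1 genes were higher in condition A as a group. Of 28 members in the authors' deposited table, 10 were higher and 0 lower, and the same numbers held when p was adjusted over the list alone. Besides FOS, EGR1 and JUN these were BTG2, ZFP36, EGR2, DUSP2, NR4A1, KLF10 and EGR3. The AP-1 genes FOSB, FOSL1, FOSL2, JUNB, JUND, ATF3, BATF and BATF3 were not called. Their log2 ratios ran from -0.63 for BATF3 to 0.39 for JUNB in the authors' deposited table. ZFP36, which binds AU-rich messenger RNAs, had a log2 ratio of 0.85 and EGR2 of 0.73 in the authors' deposited table. The median log2 ratio of the 23 members with a mean of at least 50 was 0.39. A cameraPR test of the list gave an adjusted p of 9.51e-19 (0.0288 with an estimated correlation, and 0.0534 with an estimated correlation among genes with a mean of at least 100).

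Cholesterol synthesis genes were lower in condition A. Of 24 members in the authors' deposited table, 14 were lower and 0 higher (20 lower and 0 higher when adjusted over the list alone), and 22 of the 24 had a log2 ratio below 0. FDPS, which makes farnesyl diphosphate, had a log2 ratio of -0.83, ACAT2 -0.82 and HMGCS1, the synthase upstream of HMG-CoA reductase, -0.86 in the authors' deposited table, with DESeq adjusted p from 1.39e-09 to 1.33e-06. The list's median was -0.42 and its cameraPR adjusted p 2.33e-35 (1.51e-05 with an estimated correlation). Glycolysis and hypoxia genes were lower by a smaller median of -0.11, with 8 of 28 members lower and 0 higher in the authors' deposited table (10 lower and 1 higher when adjusted over the list alone). PFKFB4, a regulator of glycolytic flux, had a log2 ratio of -1.12, ALDOC, an aldolase, -0.77 and VEGFA, the vascular growth factor, -0.53 in the authors' deposited table. The cameraPR adjusted p of this list was 4.64e-07, and 4.48e-08 with an estimated correlation. The estimate was below 0 and was set to 0, which is laxer than the preset 0.01.

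**Figure D2:**
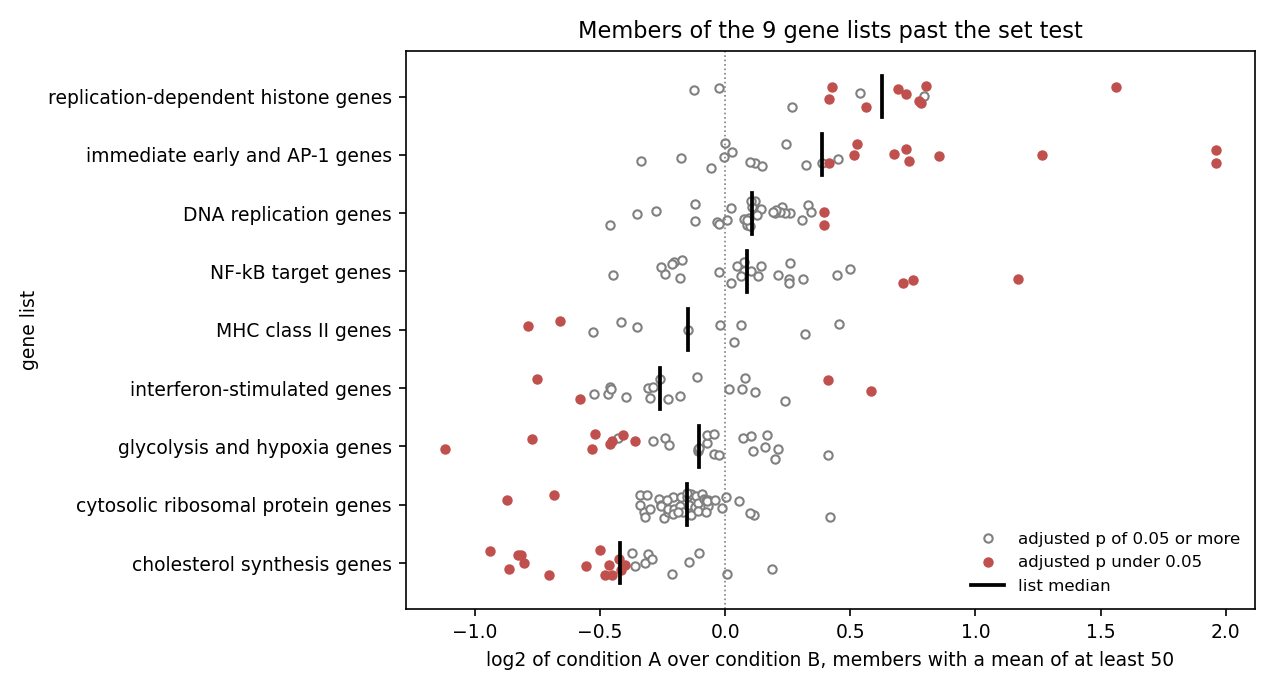
Log2 ratio of condition A over condition B (horizontal axis) of list members with a mean of at least 50, for the 9 gene lists past the cameraPR test, with filled points for deposited adjusted p under 0.05 and a black bar at each list's median. The medians ran from -0.42 for cholesterol synthesis to 0.63 for replication-dependent histone genes.

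Replication-dependent histone genes were higher in condition A, with 11 of 22 members higher and 0 lower in the authors' deposited table (13 higher and 1 lower when adjusted over the list alone). HIST2H2BE had a log2 ratio of 1.56, HIST1H2BJ 0.78, HIST1H3B 1.64 and HIST1H4H 0.72 in the authors' deposited table. The list's median was 0.63 and its cameraPR adjusted p 8.06e-16 (0.000362 with an estimated correlation). Histone genes of the same class are alike in sequence, so reads can be shared between them. DNA replication genes had a small positive median of 0.11, with 2 members, E2F2 among them, higher and 0 lower among 31 in the authors' deposited table (3 higher and 2 lower when adjusted over the list alone). That list's cameraPR adjusted p was 0.00167, and adjusted p = 0.25 with an estimated correlation. None of 28 mitotic cell cycle genes and none of 32 MYC-activated growth genes passed the threshold in the authors' deposited table (1 mitotic gene higher, and 0 growth genes, when adjusted over the list alone), and their cameraPR adjusted p were 0.209 and 0.757.

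Cytosolic ribosomal protein genes had slightly lower values in condition A, with 41 of 46 log2 ratios below 0 and a median of -0.15, but only RPL15 and RPS12 were called, with log2 ratios of -0.87 and -0.68 in the authors' deposited table (the same 2 lower and 0 higher when adjusted over the list alone). The list's cameraPR adjusted p was 5.39e-11, and adjusted p = 0.225 with an estimated correlation. RPL15 has processed pseudogenes with which reads can be shared, and RPL15P3 and RPL15P22 were lower too, with log2 ratios of -1.07 each in the authors' deposited table.

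Genes of B cell stages moved in both directions. Among 23 germinal centre genes in the authors' deposited table, 4 were lower, LRMP, MYBL1 and DENND3 among them, and KLHL6 and BACH2 were higher (7 lower and 5 higher when adjusted over the list alone). PRDM1, the regulator of plasma cell differentiation, had a log2 ratio of 0.81 and IRF4, which acts with it, 0.41 in the authors' deposited table. These were the 2 members of 23 plasma cell genes called, both higher (2 higher and 2 lower when adjusted over the list alone). Of 27 B cell receptor and identity genes, 4 were lower, CD180, CD72 and CR2 among them, and CD79B and FCRLA were higher in the authors' deposited table (4 lower and 4 higher when adjusted over the list alone). CD180, a Toll-like receptor homologue, had a log2 ratio of -0.73 and CD72 of -0.55 in the authors' deposited table. The cameraPR adjusted p was 0.757 for germinal centre, 0.915 for plasma cell and 0.556 for B cell receptor and identity genes. Within the PRDM family, PRDM1 and PRDM15 were higher and PRDM11 lower among 15 members in the authors' deposited table (4 higher and 1 lower when adjusted over the list alone, cameraPR adjusted p = 0.236).

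Immune response genes were mixed. The interferon-stimulated genes MX1, IFIT1, IFIT5 and IFITM1 were lower and ISG20 and OAS3 higher among 32 members in the authors' deposited table (13 lower and 2 higher when adjusted over the list alone). MX1 had 26.5 normalised reads in condition A and 64.0 in condition B and IFIT1 18.8 and 49.1 in the authors' deposited table, so these were low in both. The interferon list's cameraPR adjusted p was 1.06e-06, 4.63e-08 with an estimated correlation and 0.163 among genes with a mean of at least 100. Of 28 NF-kB target genes, PIM1, a serine and threonine kinase, and the chemokine genes CCL3 and CCL4 were higher and 0 lower in the authors' deposited table (3 higher and 0 lower when adjusted over the list alone), with log2 ratios of 0.71, 0.75 and 1.17. That list's cameraPR adjusted p was 0.0161, adjusted p = 0.572 with an estimated correlation, 0.0513 among genes with a mean of at least 10 and 0.133 on ranks. HLA-DQA1 and HLA-DQB1, which encode the chains of an antigen-presenting dimer, were the 2 of 12 MHC class II genes called, with log2 ratios of -0.79 and -0.66 in the authors' deposited table (2 lower and 1 higher when adjusted over the list alone). The MHC class II list's cameraPR adjusted p was 0.04, with adjusted p = 0.178 with an estimated correlation, 0.188 and 0.355 among genes with a mean of at least 10 and 100, and 0.133 on ranks. HLA class II genes are alike in sequence, and reads may have been split between them.

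Among 29 cytokine and chemokine signalling genes, CXCR4, IL4R, CCL3 and CCL4 were higher and TNFRSF13C, the BAFF receptor, lower in the authors' deposited table (6 higher and 4 lower when adjusted over the list alone). CXCR4, a chemokine receptor, and IL4R had log2 ratios of 0.58 each in the authors' deposited table, and TNFRSF13C -0.64. Among 27 adhesion and migration genes, CXCR4, RHOH, SELPLG and RGS1 were higher and VIM and ITGB2 lower in the authors' deposited table (7 higher and 5 lower when adjusted over the list alone). The cameraPR adjusted p was 0.209 for the cytokine and chemokine list and 0.73 for the adhesion and migration list.

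HSPA6 and HSPB1 were the 2 of 16 heat shock genes called, both higher in the authors' deposited table (3 higher and 0 lower when adjusted over the list alone, cameraPR adjusted p = 0.101). HERPUD1, of endoplasmic reticulum protein degradation, and PPP1R15A, a phosphatase subunit, were higher with log2 ratios of 0.84 and 0.72, and DDIT4, TRIB3 and CHAC1 lower, among 28 unfolded protein response and ATF4 genes in the authors' deposited table (3 higher and 7 lower when adjusted over the list alone, cameraPR adjusted p = 0.221). Of 26 p53 target genes BTG2 and PHLDA3 were higher and CCNG1 lower in the authors' deposited table (3 higher and 2 lower when adjusted over the list alone, cameraPR adjusted p = 0.762). PHLDA3 rested on few reads, with 12, 19 and 8 reads in the libraries of condition A and 0, 0 and 1 in condition B. BIK, a proapoptotic gene, was the 1 of 18 BCL2 family genes called, with a log2 ratio of 0.38 in the authors' deposited table (1 higher and 1 lower when adjusted over the list alone). The BCL2 family list had 13 of 17 log2 ratios above 0 among members with a mean of at least 50, and its cameraPR adjusted p was 0.0547, and 0.042 on ranks.

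Of 15 T cell and NK cell markers, TRAC, the T cell receptor alpha constant gene, was called higher, with 589.3 normalised reads in condition A and 275.6 in condition B in the authors' deposited table. TRBC2, a T cell receptor beta constant gene, had 1249 and 776.7 in the authors' deposited table (DESeq adjusted p = 0.141) and was the second gene called higher when adjusted over the list alone, where 2 were higher and 0 lower. These were the 2 markers of the list with a mean of at least 50. The list's cameraPR adjusted p was 0.221, and for these 2 genes among genes with a mean of at least 100 it was 0.00828 (0.0191 with an estimated correlation). None of 12 myeloid and none of 20 epithelial and fibroblast markers passed the threshold in the authors' deposited table, nor when adjusted over each list alone, and their cameraPR adjusted p were 0.924 and 0.698. Mitochondrially encoded genes had 0 rows and were not analysed here. Of the 24 lists tested, 9 passed a cameraPR adjusted p of 0.05, and 5 of them with an estimated correlation. The lists of immediate early, interferon-stimulated, cholesterol synthesis, glycolysis and hypoxia, and histone genes were those 5. For the interferon and the glycolysis and hypoxia lists the estimate was set to 0, so it was no stricter check. In the heat shock, MYC-activated, germinal centre, plasma cell, p53, B cell receptor and identity, and adhesion lists the median, the mean and the test differed in sign.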

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

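The limma test, the left-out libraries, the list tests with an estimated correlation and the list tests on ranks were chosen only after the data were seen. The 881 calls became 505 (181 higher and 324 lower in condition A) at an adjusted p under 0.01, 488 (180 and 308) with a 1.5-fold minimum, and 1535 (627 and 908) by limma on the recovered reads. The stricter settings give fewer by construction. With a mean of at least 10, a minimum that the limma test also used, the deposited p adjusted again gave 1177 calls (465 and 712). Part of the higher limma count may therefore come with that minimum, and the cause of the rest was not tested. With 1 library left out the limma count ran from 367 to 2183. It was 387 without library 2 of condition A, 367 without library 2 of condition B and 387 without library 3 of condition B. No other count of genes moved by over 1.5 times. PRDM11, FOS and JUN kept their call at an adjusted p under 0.01 and with each minimum mean. Their log2 ratios with any 1 library left out, which were not tested, ran from -1.01 to -0.87, 1.93 to 2.01 and 1.23 to 1.31. Of 110 named genes, 13 called at 0.05 missed an adjusted p of 0.01, among them PRDM15, IRF4, HLA-DQB1 and HSPB1. Centring turned the sign of no called gene. It decides little, because the median was -0.0018 among genes with a mean of at least 100 and centred values of single genes were not tested. The 9 lists called became 5 with an estimated correlation and 4 with that estimate among genes with a mean of at least 100. With the correlation estimated, ribosomal protein, DNA replication, NF-kB and MHC class II genes were no longer called, and among genes with a mean of at least 100 neither were immediate early and interferon-stimulated genes, while the T cell and NK cell list, with 2 genes left, was. On ranks 8 lists were called, without NF-kB (adjusted p = 0.133) and MHC class II genes (0.133) and with BCL2 family genes (0.042). The estimate allows for shared variation of a list's genes, and the cause was not tested further. For the interferon and the glycolysis and hypoxia lists it was set to 0, and so was laxer than the preset. No paired analysis was possible because the columns carry no replicate numbers. DESeq2, other size factors, count filters, the fry test and a replicate term were planned for read counts per sample and were not run. Depth limits genes with few reads, such as PHLDA3, IFIT1 and MX1.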

Other observations

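The heat stress test of the immediate early genes and the splits of the 6 libraries were chosen only after the results were seen. Immunoglobulin genes were looked at after the calls were seen and were not tested as a group. Of 114 V, D, J and C genes in the authors' deposited table, 8 were called higher and 0 lower, beside the V pseudogene IGLVI-56, also higher, and 23 of the 31 with a mean of at least 50 had a log2 ratio above 0, with a median of 0.45 and a range from -0.41 to 1.05. IGHV1-69 had 1209 normalised reads in condition A and 639.2 in condition B, and IGLV6-57 746.9 and 359.9, in the authors' deposited table. Immunoglobulin V genes are alike in sequence, and reads can be split between them. RNU6-1, a U6 small nuclear RNA gene, held 1, 1 and 0 recovered reads in condition A and 62, 56 and 41 in condition B (DESeq adjusted p = 1.42e-21 in the authors' deposited table).

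SCD, the stearoyl-CoA desaturase picked after its value was seen, had a log2 ratio of -1.16 in the authors' deposited table, beside -1.22 for FADS2. A hypothesis written before their values were seen was that other fatty acid synthesis genes regulated by SREBP proteins would be lower too. The 12 genes with a mean of at least 50, SREBF1 and TMEM97 among them, had a median log2 ratio of -0.36, and none lay above 0. THRSP and PNPLA3 were left out by this minimum, with means of 3.29 and 0.138, and both had higher means in condition A. The 95% bootstrap interval of the median ran from -0.59 to -0.20. It resamples genes and does not measure the spread between samples. SREBF1, which encodes an SREBP protein, had a log2 ratio of -0.78, FADS1 -0.73 and ELOVL6 -0.66 in the authors' deposited table, and 6 of the 12 were called lower. FASN, ACLY, ELOVL5, ME1, GPAM and TMEM97 were not called, with log2 ratios from -0.34 for GPAM to -0.11 for ME1. The values are consistent with a joint decrease of SREBP-regulated lipid genes, which remains a hypothesis.

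The cholesterol synthesis genes were lower in condition A by a median log2 ratio of -0.42. The tables argue against transcript length or GC content, since the median lay at percentile 0 of 10000 random lists matched on length, GC content and mean expression, the middle 95% of whose medians lay between -0.06 and 0.13. A single library was not decisive for the 14 members with recovered reads, whose median of -0.43 came nearest to 0 at -0.37, without library 1 of condition A. A response to the hairpin's sequence that does not run through PRDM11 may account for the pattern and stays open, because the labels give 1 plasmid for each group. PRDM11 depletion itself also stays open, since with 1 plasmid for each group it cannot be told apart from such a response. That conditions A and B are not named leaves open which of them would be the depleted one.

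The immediate early and AP-1 genes were higher in condition A by a median of 0.39, at percentile 100 of 10000 lists matched on transcript length, GC content and mean expression. With 1 library left out the median of 22 members with recovered reads, 0.35 with all libraries, came nearest to 0 at 0.22, without library 3 of condition A. That library had the smallest size factor, 0.768. Heat stress during handling stays open, because the other 14 heat shock genes with a mean of at least 50 had a median of -0.015 but went both ways, with log2 ratios of 1.13 for HSPB1 (called), 0.66 for BAG3 and 0.25 for DNAJB1 in the authors' deposited table. Another stimulus during cell handling may induce the same genes, and neither it nor the hairpin sequence was tested.

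The replication-dependent histone genes were higher in condition A by a median of 0.63. The tables argue against a bias for short transcripts, which would raise other short protein-coding genes. The median of 224 of these was -0.0031, with a 95% bootstrap interval from -0.03 to 0.02. The intervals of this paragraph resample genes, not libraries. A larger share of RNA without poly(A) tails stays open, although the median of 21 small nuclear, nucleolar and Cajal body RNAs was -0.003 and its interval, from -0.21 to 0.26, lay below the bound of 0.3 set beforehand. That bound decides little, because SNORD17, the most abundant of these with a mean of 418.2, was called higher with a log2 ratio of 0.55 in the authors' deposited table while RNU6-1 was called lower with -6.41, and the others, RNU6-1 included, had means of 20.1 to 74.4 and went both ways. Reads shared between histone copies and a difference in growth state between the cultures may still contribute and were not tested.

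For the limma test of the recovered reads, 1 of the 10 splits of the 6 libraries gave as many calls, the real one with 1535, and the highest of the others gave 0. With 10 splits a share under 0.05 cannot be reached.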
